A study of Mus musculus with 6 samples.

How the data were processed

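Total RNA of stage-matched hearts was used, and per the labels' protocols stranded poly(A) libraries were made from 300 ng of it with a TruSeq kit and read from both ends on a NovaSeq instrument. The submitters' processing notes name bcl2fastq 2.20, STAR 2.7.9a, featureCounts, Subread 2.0.1 and DESeq2 1.30.1, and the builds GRCm39 and mm39. The annotation, the strand setting of the counting and the filter on genes are not given in the sources used here. The deposited values are, per the file headers and names, normalized counts: a signal per gene that the authors made by dividing read counts by a size factor for each library. The table holds 15330 rows and 6 columns, and 5 further files repeat 1 column each with identical values.

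Each column was given to the sample whose title carries the code in its header. The files of 4 samples are recorded under the other group, a conflict within the labels, and the recorded assignment was run as an alternative. Xist, expressed from the inactive X chromosome, stood at 27484, 41997, 37516 and 40013 normalized counts in the 4 columns whose titles belong to libraries labelled female and at 58.6 and 42.1 in those labelled male. No gene of the Y chromosome on the sex list was among the rows, and neither was any of the mitochondrial transcripts. The sex check does not tell replicates 1 and 2 of the groups apart, since all 4 are female.

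The values in each column were whole multiples of the value of 1 read, for 100% of the values within a tolerance of 0.01, so reads could be recovered: 25583210, 32028443 and 32043595 in wild-type replicates 1 to 3, and 26679958, 30117718 and 26016264 in deletion replicates 1 to 3. The main test kept to the deposited values, as fixed before the data were examined: limma-trend (limma 3.58.1, R 4.3.3) on log2(normalized count + 1), with genes of a mean of at least 10. That filter removed no gene, since the lowest mean was 15.4. Fold changes are differences of mean values on this scale, deletion minus wild-type. The pseudocount shrinks the log ratio of low values, but a difference of mean logs can also exceed the log of the ratio of means where low libraries vary, as for Slit1 with 2.88 against 2.64 in edgeR. P-values are two-sided and Benjamini-Hochberg adjusted, with 0.05 as threshold. The test was tried on simulated counts for all 15330 genes, with 200 changed in each of 5 runs: it called 57.0% of genes changed 1.5-fold, 80.3% of those changed 2-fold and 99.4% of those changed 4-fold, and 8.69% of its calls were false. That false share is above the threshold of 0.05. The simulated genes varied independently, without a trend with length and GC content or a correlation between genes, so these shares need not hold for the data.

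The 25 gene lists were fixed before the data were examined. Of these 22 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Named genes followed a rule fixed at the same time: the genes of the Hand2 locus list; the 12 with the largest fall and the 12 with the largest rise among those past the threshold with a mean of at least 50 normalized counts in the higher group and no overlap between groups, without gene models, pseudogenes and sex genes; and from each list up to 4 members past the threshold by smallest p or, where none passed, up to 2 given as values. A gene that met the rule is not reported here. Symbols were found for 1382 of 1598 rows that carried an Ensembl identifier. The reference held was GENCODE M21 on GRCm38, another build than the authors', so it served only for names, for which genes neighbour Hand2 within 1 Mb, and for the length and GC content of the longest transcript, known for 96.9% of genes and 97.2% of called genes.

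Alternatives covered the pseudocount, the filter, the scaling, the variance model, edgeR's quasi-likelihood test (4.0.16) and DESeq2 (1.42.0) on the recovered reads, sex, a replicate block, the recorded file assignment, the neighbourhood's width, the list test and each library left out. Removal of a length and GC trend was added after seeing the data: in each library the deviations from the gene means were regressed on natural splines with 4 degrees of freedom each, and the fitted part was subtracted. Other splits of the libraries numbered 10 with the real one included.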

Results

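RNA was sequenced from micro-dissected hearts of mouse embryos at embryonic day 9.5, when the heart tube has looped and its chambers, valve cushions and outflow tract are forming. There were 2 groups of 3 libraries: wild-type hearts, and hearts homozygous for a CRISPR-Cas9 deletion of 373 kb upstream of Hand2, called the H2-URI. Hand2 is a basic helix-loop-helix transcription factor of the developing heart, limb and branchial arches. Each group had 2 libraries labelled female and 1 labelled male, and all 6 carried batch number 1. The libraries held between 25583210 and 32043595 reads over 15330 genes. The labels do not say whether a library came from 1 heart or from a pool, so the p-values measure the spread between these libraries. The question put to the data was how far Hand2 expression in the heart depends on this interval and which other transcripts differ without it.

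Hand2 was expressed at 4036 ± 328 normalized counts (SD, n = 3) in wild-type hearts and at 1115 ± 78.3 (SD, n = 3) in the deletion, which is 27.6% of the wild-type mean. The wild-type libraries held 3911, 3789 and 4407 normalized counts and the deletion libraries 1025, 1158 and 1163. The log2 fold change was −1.85 (SE 0.08, adjusted p = 1.51e-05, limma). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 allows. Hand2 transcripts were measured in all 3 deletion libraries. These values rest on giving each column of the deposited table to the sample whose title carries the column's code. For 4 of the 6 files the recorded sample belongs to the other group, and under that record the Hand2 log2 fold change was 0.57 and 0 genes passed in limma, with 414 at an unadjusted p under 0.05. Code and record agree for replicate 3, at 4407 normalized counts in the wild-type and 1163 in the deletion library. By Hand2 level the columns in conflict fell with these libraries as their codes say. That comparison rests on a single undisputed library per group.

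Among the 10 measured genes within 1 Mb of Hand2, 2 passed the threshold, both lower in the deletion. Whether the deletion removes part of either gene was not examined, so lost sequence and lost regulation cannot be told apart for them. Hand2os1, the antisense long non-coding RNA beside Hand2, fell from 2574 ± 480 to 762 ± 46.1 normalized counts (SD, n = 3; log2 fold change −1.74, adjusted p = 1.52e-04, limma). The strand setting of the counting was not stated, so reads of Hand2 and of Hand2os1 cannot be told apart where they overlap. The long non-coding RNA Gm34030 fell from 135 ± 17.9 to 63.3 ± 11.05 (SD, n = 3; log2 fold change −1.09, adjusted p = 0.0174, limma). It was the neighbour lost from the count, which became 1, without wild-type replicate 3, without deletion replicate 2 and without deletion replicate 3. The protein-coding neighbours had log2 fold changes of 0.02 for Sap30, −0.16 for Hmgb2, −0.14 for Galnt7, −0.17 for Fbxo8 and 0.10 for Cep44, none past the threshold. Hpgd, farther away, had a log2 fold change of 0.48 (adjusted p = 0.514, limma).

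**Figure D1:**
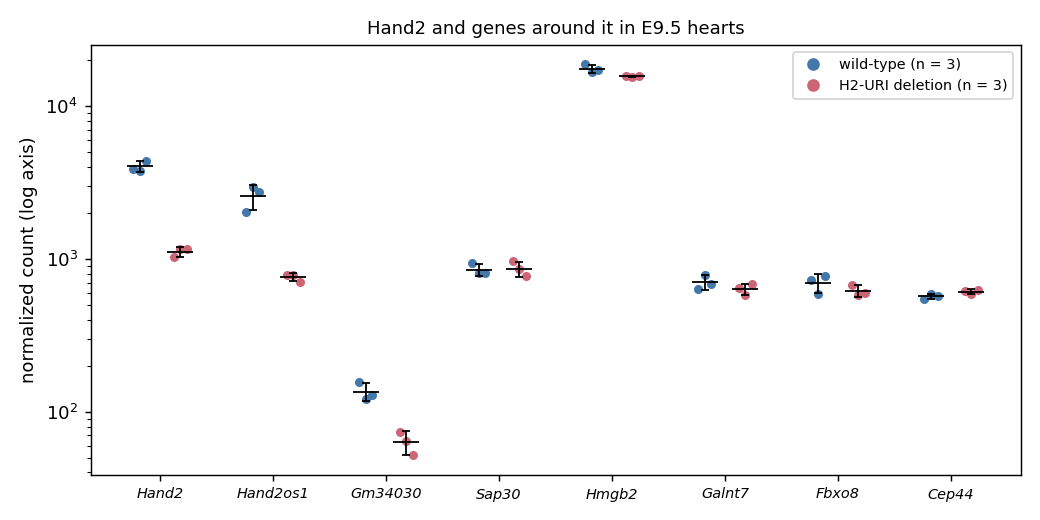
Normalized counts (log axis) of Hand2 and of genes around it in each of 3 wild-type and 3 deletion libraries, with points for libraries and bars for mean ± SD. Hand2 lies between 3789 and 4407 in wild-type libraries and between 1025 and 1163 in deletion libraries.

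Over all genes, 230 were lower and 237 higher in the deletion in limma at an adjusted p under 0.05, of which 58 and 41 changed by at least 2-fold. The steepest falls among genes chosen by the fixed rule began with Ccl2, a chemokine that draws monocytes, which fell from 101 ± 26.4 to 5.32 ± 5.03 normalized counts (SD, n = 3; log2 fold change −4.33). Acap1 fell from 316 ± 37.6 to 31.5 ± 6.45 (−3.30). Nt5e, the ectoenzyme that makes adenosine from AMP, fell from 170 ± 17.7 to 20.4 ± 2.08 (−2.99). Tdgf1, a co-receptor for Nodal expressed in the outflow tract, fell from 634 ± 26.6 to 132 ± 49.5 (log2 fold change −2.33). Wnt4, a secreted Wnt ligand, fell from 265 ± 12.2 to 63.7 ± 8.49 (−2.04). Etv2, a transcription factor of early endothelial and blood progenitors, fell from 137 ± 29.2 to 35.2 ± 3.87 (−1.91). The other genes in this group were Lgals9 (−2.26), Clec4g (−2.21), Nostrin (−2.06), Bace2 (−1.98), Colec11 (−1.94) and Adh6b (−1.87).

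The steepest rises were in Slit1, a guidance ligand for Robo receptors, from 10.8 ± 8.29 to 65.6 ± 4.46 normalized counts (SD, n = 3; log2 fold change 2.88), Slc6a7 from 11.7 ± 8.56 to 54.6 ± 2.96 (2.33) and Ly6h from 16.3 ± 1.97 to 67.8 ± 13.7 (1.98). Robo4, an endothelial receptor of the Robo family, rose from 32.3 ± 19.3 to 112 ± 4.06 (1.91). Tbx1, a T-box factor of the pharyngeal region and second heart field, rose from 45.8 ± 34.8 to 145 ± 20.7 (1.90), with an adjusted p of 0.0495 in limma and no call in edgeR. Itga2, the collagen-binding integrin alpha 2, rose from 57.8 ± 6.12 to 214 ± 16.4 (1.87). Tll1, a metalloprotease of the Bmp1 family, rose from 178 ± 5.26 to 577 ± 48.9 (1.68). Sost, a secreted antagonist of Wnt signalling, rose from 371 ± 24.9 to 1098 ± 68.1 (1.56). Zfp366 (1.84), Tmem255a (1.64), Pls1 (1.62) and Sema3g (1.32) completed the group.

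**Figure D2:**
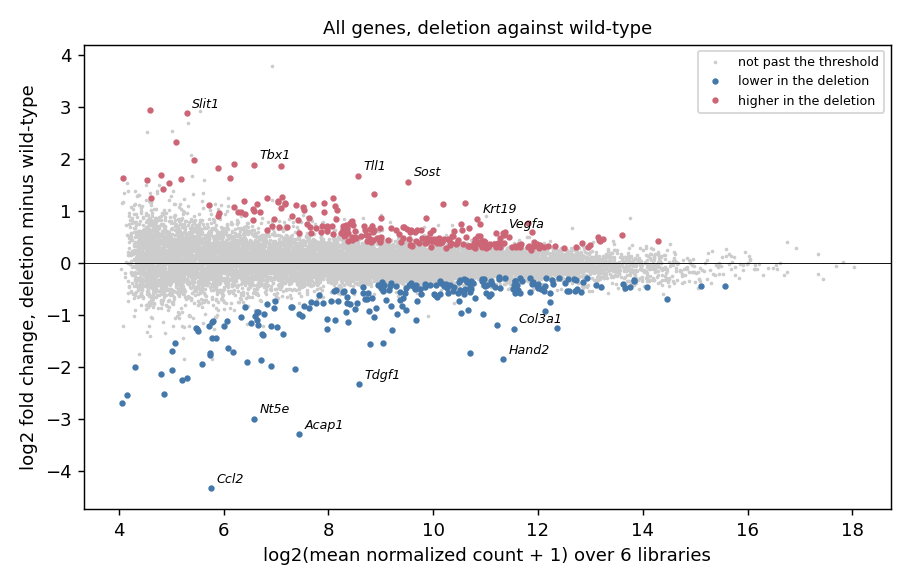
Log2 fold change of each of 15330 genes, deletion minus wild-type, against the log2 of its mean normalized count plus 1 over the 6 libraries. Blue points are the 230 genes lower and red points the 237 higher in the deletion at an adjusted p under 0.05 in limma, and grey points did not pass.

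The number of calls changed when a library was left out. It was 616 without wild-type replicate 1, 1161 without wild-type replicate 2, 168 without wild-type replicate 3, and 138, 103 and 165 without deletion replicates 1, 2 and 3, against 467 with all 6. Each such fit has fewer samples, so a fall in calls cannot be told apart from lost power. A call lost there does not by itself point to the library left out. The rises without wild-type replicates 1 and 2 are not of that kind. Of the 65 named genes past the threshold, 26 also passed with each library left out in turn: Hand2, Hand2os1, Ccl2, Acap1, Nt5e, Tdgf1, Nostrin, Wnt4, Bace2, Colec11, Etv2, Adh6b, Ly6h, Itga2, Zfp366, Tll1, Sost, Sema3g, Has2, Col3a1, Tnc, Nid1, Krt19, Gpm6a, Mrc1 and Vegfa. Every other named call was lost without at least 1 library. The groups did not overlap for any called gene, nor for 27.4% of all genes, where chance gives 10%. Higher calls made up 50.7% of the total, 65.3% after rescaling to equal totals without haemoglobin, and 38.5% after a trend with transcript length and GC content was removed from each library. That trend differed between libraries: genes called higher had a median transcript length of 4525 bases and a GC content of 53.8%, genes called lower 3003 bases and 48.2%, and all genes 3180 bases and 49.7%. After its removal 194 of the 230 lower and 154 of the 237 higher calls remained, among 305 lower and 191 higher calls then made.

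Of 22 gene lists fixed beforehand, camera with a preset correlation called 9, 6 higher and 3 lower in the deletion. No list passed with an estimated correlation, where the lowest adjusted p was 0.358 and 1 list had an unadjusted p under 0.05, or in fry, where the lowest was 0.0958 and 8 did. Another split of the 6 libraries, the one that follows the recorded files, gave 11 list calls with the preset correlation, so the counts of single genes carry the account of each list below. Of the 9 lists called, 3 were also called with each library left out in turn: hypoxia and glycolysis, epicardium, and the stress response. Over the 21 alternatives that kept camera, its preset correlation and the groups, 2 of the 9 held their call in all, hypoxia and glycolysis and the stress response, and 6 of the 13 other lists were called in at least 1. The robust variance and the filter without a minimum left camera's values unchanged, so they could not move a call. With DESeq2 the preranked form of camera was run on its test statistics. In 19 of the 22 lists the number of members called higher or lower moved by over 1.5 times without at least 1 library, where a fall can come from the smaller fit.

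In the extracellular matrix list 6 of 25 measured members fell and 0 rose (12 lower and 3 higher, Fn1, Col4a2 and Col2a1, adjusted over the list alone; camera adjusted p = 0.00507, and adjusted p = 0.417 with an estimated correlation). Col3a1, a fibrillar collagen of cushion and vessel wall, fell from 4178 ± 424 to 1751 ± 309 normalized counts (SD, n = 3; log2 fold change −1.26), the matrix glycoprotein Tnc from 3329 ± 733 to 1441 ± 252 (−1.20) and the basement membrane protein Nid1 from 5069 ± 156 to 3598 ± 248 (−0.50). In the list of atrioventricular canal and cushion mesenchyme, 6 of 27 members fell and 1 rose (10 lower and 3 higher adjusted over the list alone; camera adjusted p = 0.0374, and adjusted p = 0.358 with an estimated correlation). Has2, the hyaluronan synthase needed for cardiac cushions, fell from 2662 ± 215 to 1761 ± 50.3 (log2 fold change −0.59), Twist1 from 464 ± 162 to 202 ± 14.5 (−1.14), Msx1 from 485 ± 55.3 to 323 ± 30.6 (−0.58) and Foxc1 from 273 ± 19.7 to 161 ± 33.9 (−0.77). The last 3 are transcription factors of mesenchyme, and each lost its call without at least 1 deletion library. With each library left out in turn, 4 to 8 matrix genes and 1 to 6 cushion genes were lower, and without wild-type replicate 2 camera called neither list (adjusted p = 0.0650 and 0.180). The cushion list was also not called with a mean of at least 50 (adjusted p = 0.0549) or without an intensity trend (adjusted p = 0.0581).

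Of 30 measured members of the endocardium and endothelium list, 6 fell and 3 rose (11 lower and 10 higher adjusted over the list alone), and camera called no direction (adjusted p = 0.629). With each library left out in turn 1 to 9 were lower and 0 to 6 higher, with 0 higher without wild-type replicate 3 or any 1 of the deletion libraries. Eng, a co-receptor for TGF-beta ligands, fell from 3541 ± 150 to 2638 ± 125 normalized counts (SD, n = 3; log2 fold change −0.42), and Nrg1, the endocardial ligand of trabeculation, from 474 ± 104 to 252 ± 19.4 (−0.89). The tight junction gene Cldn5 rose from 80.6 ± 21.7 to 180 ± 16.4 (log2 fold change 1.18). Pecam1 and Cdh5, general endothelial markers looked at after their values were seen, had 2472 ± 115 and 4261 ± 259 in wild-type and 2470 ± 133 and 4250 ± 109 in deletion hearts. In the list of Notch and neuregulin signals 2 of 18 members rose and 1, Nrg1, fell (7 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.114, and called higher without wild-type replicate 1, adjusted p = 0.0409). The neuregulin receptor gene Erbb2 had a log2 fold change of 0.35 and Mfng, a glycosyltransferase that modifies Notch, 0.83. The call of Erbb2 ended after the length and GC trend was removed.

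Of 30 measured sarcomere genes 0 were called in limma over all genes, with 6 at an unadjusted p under 0.05, against 1 in edgeR and 6 in DESeq2. Adjusted over the list alone 1 was higher, and camera gave an adjusted p of 0.454 with a list median of 0.03. Camera called the list higher after quantile normalization (median 0.10, adjusted p = 0.0230), in the 4 female libraries (0.10, adjusted p = 0.00217) and without wild-type replicate 3 (0.08, adjusted p = 0.0192), so whether it moved depended on the scaling and the libraries. Myoz2, a Z-disc protein, had 245 ± 54.9 normalized counts in wild-type and 437 ± 103 in deletion hearts (SD, n = 3; log2 fold change 0.83, adjusted p = 0.0505, limma), and Ankrd1 a log2 fold change of 0.37. Of 20 ventricular and trabecular genes, 2 rose and 0 fell (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.926): Nppb, the gene of B-type natriuretic peptide, from 2671 ± 678 to 4510 ± 695 (0.78) and the potassium channel subunit Kcne1 from 295 ± 6.59 to 399 ± 18.2 (0.44). Of 13 atrial and sinus venosus genes 1, the atrial potassium channel Kcna5, rose from 643 ± 112 to 964 ± 61.1 (0.60), and 2 were higher adjusted over the list alone (camera adjusted p = 0.0472, and adjusted p = 0.417 with an estimated correlation). Of 20 genes of ion channels, calcium handling and conduction, 3 rose and 0 fell (4 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0101, and adjusted p = 0.527 with an estimated correlation), among them the potassium channel gene Kcnh2 (log2 fold change 0.37) and Casq2, which binds calcium in the sarcoplasmic reticulum (0.64). After removal of the length and GC trend camera no longer called the atrial (adjusted p = 0.0888) or ion channel (adjusted p = 0.198) list, and Kcne1 and Kcnh2 no longer passed. The ion channel list was also not called without wild-type replicate 1 (adjusted p = 0.0584). The atrial list was not called after rescaling to equal medians (adjusted p = 0.0524), without an intensity trend (0.108), or without wild-type replicate 2 (0.178), deletion replicate 1 (0.0804) or deletion replicate 3 (0.0708).

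Among 26 cardiac transcription factors, 3 rose and 0 fell (6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0201, and adjusted p = 0.358 with an estimated correlation). They were Tbx1, Tbx3, a T-box repressor of chamber differentiation, from 901 ± 16.8 to 1212 ± 118 normalized counts (SD, n = 3; log2 fold change 0.42), and Srf from 3396 ± 54.7 to 4061 ± 67.7 (0.26). After removal of the length and GC trend the list was not called (adjusted p = 0.172), nor were Tbx3 and Srf, and 1 member was higher and 2 were lower. The list was also not called without wild-type replicate 1 (adjusted p = 0.0703). In the list of second heart field and outflow tract, 3 of 22 members fell, Tdgf1, Foxc1 and Rgs5 (log2 fold change −0.40), and 2 rose, Tbx1 and Sema3c (0.48), a semaphorin of the outflow tract (5 lower and 5 higher adjusted over the list alone; camera adjusted p = 0.871). Of 19 BMP and TGF-beta genes 3 rose, Smad7 (0.45), Bmp7 (0.30) and Bmp6 (0.53), and 1 fell, Tgfb1 (−0.51), with 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.597). The calls of Rgs5, Smad7 and Bmp7 ended after the trend was removed.

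In the hypoxia and glycolysis list 7 of 26 measured members rose, 0 fell and 19 did not pass (12 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.28e-07, and adjusted p = 0.358 with an estimated correlation). Vegfa, the main angiogenic growth factor, rose from 2069 ± 83.6 to 3073 ± 30.6 normalized counts (SD, n = 3; log2 fold change 0.57, adjusted p = 0.00172, limma). The glucose transporter gene Slc2a1 rose from 17165 ± 458 to 22947 ± 1059 (0.42). The glycolytic enzyme gene Pfkp rose from 7963 ± 433 to 10745 ± 597 (0.43) and the collagen prolyl hydroxylase gene P4ha2 from 972 ± 29 to 1273 ± 7.04 (0.39). The 19 members that did not pass had log2 fold changes from −0.16 for Higd1a to 0.52 for Ndrg1. Glycolytic enzyme genes among them, named after their values were seen, had 0.36 for Pfkl, 0.25 for Hk1, 0.18 for Hk2, 0.14 for Aldoa, 0.12 for Pgk1, 0.12 for Gpi1, 0.08 for Tpi1, 0.08 for Ldha, 0.01 for Gapdh and 0.0053 for Eno1, and Pfkl and Hk1 were higher adjusted over the list alone. The number of members that rose was 1 without deletion replicate 1 or 2, 3 without wild-type replicate 3 or deletion replicate 3, and 10 without wild-type replicate 1. Of 15 genes of the integrated stress and unfolded protein response 3 fell and 0 rose (8 lower and 0 higher adjusted over the list alone; camera adjusted p = 6.15e-04, and adjusted p = 0.358 with an estimated correlation): Asns (log2 fold change −0.60), the chaperone gene Hspa5 (−0.44) and Pdia4 (−0.30), the last not called by edgeR or after the length and GC trend was removed. The falls numbered 0 to 8 with each library left out, with 0 without deletion replicate 1 or 2 and 8 without wild-type replicate 2. They numbered 1 after quantile normalization, 1 after rescaling to equal medians and 0 without an intensity trend. Of 11 immediate early genes 1, Ier3, rose (0.83), with 3 higher adjusted over the list alone (camera adjusted p = 0.0201, and adjusted p = 0.358 with an estimated correlation). That list was not called without wild-type replicate 2 (adjusted p = 0.0889) or deletion replicate 2 (adjusted p = 0.0669). Of 16 p53 target genes 1, Ddit4, rose (0.57; not called by edgeR), and 1 was higher adjusted over the list alone (camera adjusted p = 0.530). Of 26 cell cycle genes 0 passed in limma, over all genes or adjusted over the list alone (5 at an unadjusted p under 0.05, 0 in edgeR and 1 in DESeq2; camera adjusted p = 0.316, and called lower in the 4 female libraries, adjusted p = 0.0324). Cdk1 and Pcna had log2 fold changes of −0.28 and −0.20.

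Markers of other cells of the dissection were read in the same way. Of 12 measured epicardial and proepicardial markers 2 rose and 0 fell (5 higher adjusted over the list alone; camera adjusted p = 6.15e-04, and adjusted p = 0.411 with an estimated correlation): Krt19 from 1299 ± 51.7 to 2351 ± 27.2 normalized counts (SD, n = 3; log2 fold change 0.86) and Gpm6a from 66.2 ± 12.3 to 158 ± 20.3 (1.25). The list median was 0.60, and 0.42 to 0.85 with each library left out, where 2 to 6 members rose. In the 4 female libraries it was 0.33, with 1 member higher, and camera did not call the list (adjusted p = 0.0502). Of 6 leukocyte markers 1, the mannose receptor gene Mrc1, rose from 117 ± 13.7 to 248 ± 33.1 (1.08), with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.597). Ets1 fell (−0.30) among 9 neural crest markers (0 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.629), and Nes had a log2 fold change of 0.31 among 8 neural markers (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0594), a call that ended after the trend was removed. Camera called the neural list higher with the replicate block (adjusted p = 0.0183), with sex as a covariate (0.0296), without wild-type replicate 1 (0.0238) and without deletion replicate 2 (0.0288). Of 15 endoderm and liver bud markers 0 passed in limma, over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05, 0 in edgeR and 0 in DESeq2; camera adjusted p = 0.757). That count rested on single libraries: without wild-type replicate 1, 3 members were higher and camera called the list (adjusted p = 0.0130), and without wild-type replicate 2, 2 were lower. Pax9 had 11.4 ± 12.7 and 66.9 ± 46.7, and Apoa1 125 ± 83.9 and 47.6 ± 19.2. Of 18 primitive erythroid markers 0 passed in limma, edgeR or DESeq2, and 0 had an unadjusted p under 0.05 in limma (0 adjusted over the list alone; camera adjusted p = 0.597), with log2 fold changes of −0.91 for Hbb-bt and 0.10 for Tfrc. Camera called that list higher without wild-type replicate 2 (adjusted p = 0.0426) and without deletion replicate 1 (adjusted p = 1.65e-04), and lower in the 4 female libraries (median −0.78, adjusted p = 1.77e-04), so its direction turned with the libraries used. The share of haemoglobin transcripts ranged from 0.403% to 1.22% in wild-type and from 0.298% to 1.59% in deletion libraries. The nuclear RNA Malat1 stood at 5626, 13430 and 11534 normalized counts in the wild-type libraries and at 17788, 19241 and 15417 in the deletion libraries, and every wild-type library lay below every deletion library (log2 fold change 0.87, adjusted p = 0.103, limma).

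**Figure D3:**
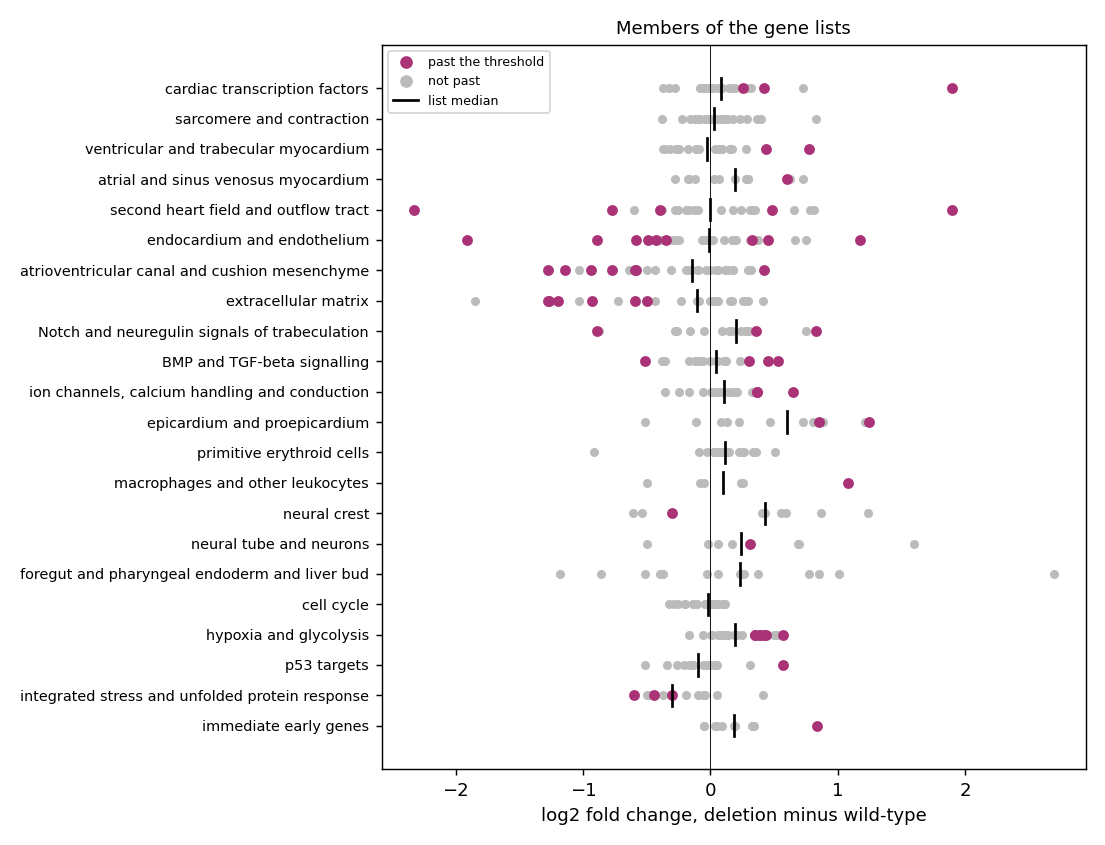
Log2 fold change, deletion minus wild-type, of each measured member of the 22 tested gene lists, 1 row per list. Coloured points passed an adjusted p under 0.05 over all genes in limma, grey points did not, and black bars mark the list medians; 7 hypoxia and glycolysis genes and 6 extracellular matrix genes are coloured.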

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

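The fall of Hand2 kept its direction and its side of the threshold under 21 alternatives, with log2 fold changes from −1.94 to −1.79 and adjusted p from 1.19e-83 to 0.00354. The exception was the recorded file assignment. With it Hand2 was at 0.57, 0 genes were lower, 0 higher and 0 neighbours past the threshold, and 61 other named genes changed sign, none past the threshold: Hand2os1 0.44, Ccl2 2.11, Acap1 1.16, Nt5e 0.98, Tdgf1 0.42, Lgals9 1.28, Clec4g 0.99, Nostrin 0.74, Wnt4 0.57, Bace2 0.92, Colec11 0.84, Etv2 0.45, Adh6b 0.68, Slc6a7 −0.53, Ly6h −0.90, Robo4 −0.23, Itga2 −0.61, Zfp366 −0.64, Tll1 −0.63, Pls1 −0.41, Sost −0.53, Sema3g −0.66, Tbx3 −0.24, Srf −0.061, Kcne1 −0.19, Nppb −0.35, Kcna5 −0.31, Sema3c −0.25, Foxc1 0.40, Rgs5 0.16, Eng 0.065, Cldn5 −0.19, Nrg1 0.057, Has2 0.16, Twist1 0.60, Msx1 0.18, Col3a1 0.64, Tnc 0.64, Nid1 0.24, Erbb2 −0.20, Mfng −0.19, Tgfb1 0.25, Smad7 −0.21, Bmp7 −0.12, Bmp6 −0.12, Kcnh2 −0.11, Casq2 −0.35, Krt19 −0.34, Gpm6a −0.41, Mrc1 −0.55, Ets1 0.10, Nes −0.16, Vegfa −0.20, Pfkp −0.23, P4ha2 −0.10, Slc2a1 −0.16, Ddit4 −0.0027, Asns 0.43, Hspa5 0.0017, Pdia4 0.072 and Ier3 −0.32. These changes of sign were counted only among named genes past the threshold in the main test. The recorded assignment exchanges 2 libraries of each group, which by its construction carries a part of each difference over with the opposite sign. Against 230 lower and 237 higher genes, there were 73 and 73 without an intensity trend in the variance, 600 and 539 with DESeq2, which gave no adjusted p for 892 genes, and 23 and 12 with the 4 female libraries, which are fewer samples and left 1 neighbour past the threshold. Rescaling to equal totals without haemoglobin gave 393 higher genes. The cause of the other changes was not tested. With each library left out in turn, lower genes numbered 61 to 695, higher genes 42 to 466, neighbours past the threshold 1 to 2 and list calls 6 to 10. The lists called fell from 9 to 0 with an estimated correlation and to 0 in fry. The filter without a minimum removed no gene and so tested nothing.

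The replicate numbers are shared between groups, but deviations of libraries with the same number correlated at −0.03, −0.11 and −0.10 across genes, so the numbers do not pair them. Among the other pairs the correlation was 0.28 for wild-type 1 with deletion 2, 0.30 for wild-type 2 with deletion 3 and 0.28 for wild-type 3 with deletion 1. The rest lay between −0.23 and −0.19. The positive pairs had like ranks of haemoglobin share, at 0.701% and 0.761%, 1.22% and 1.59%, and 0.403% and 0.298%. No alternative modelled these pairs, and their cause was not tested. With the number as a block 110 genes were lower and 96 higher, and the list calls numbered 10. No gene passed a test of whether the deletion's effect differed between the sexes in limma, where 651 had an unadjusted p under 0.05, and with 1 male library per group that test has little power. At this depth the simulated test missed many genes that changed 1.5-fold, so a gene not called is not shown to be unchanged.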

Other observations

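The arterial and tip gene list, the list-level bound on the share of endothelial cells, the slopes of length and GC and the comparison with genes induced by handling were chosen after related results had been seen, and so was the removal of the length and GC trend; the values of the arterial and tip genes themselves had not been seen when their test was set.

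The real grouping of the 6 libraries called 467 genes, and the highest of the other splits called 0. Each other split mixes both groups on either side, so a difference between the groups adds to the spread within its sides. Few gene calls there were thus built in, and the 0 does not measure how many arise without a deletion effect. The real grouping called 9 lists with the preset correlation, while the highest of the other splits called 11, and 2 of the 10 splits gave as many as the real one. With 10 splits, of which 1 is the real one, no share under 0.05 can be reached. For lists, a call at the preset correlation did not single out the deletion in these libraries.

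Genes called higher were longer and richer in GC than genes called lower. The slope of log2 value on log2 transcript length was −0.091, 0.012 and −0.044 in the wild-type libraries and 0.040, 0.033 and 0.049 in the deletion libraries, so the groups did not overlap, yet the range within wild-type was 1.26 times the difference between the group means. The slopes on GC content, per 10 points, were 0.052, −0.067 and −0.12 in wild-type and 0.020, 0.11 and 0.015 in deletion libraries, so here the groups overlapped, and the range within wild-type was 1.89 times the difference. A bias between libraries is therefore a candidate source of part of the trend in both. An effect of the deletion on long genes stays open, since the length slopes also follow the groups, while the GC slopes do not. As the whole cause of the calls such a bias is argued against by the 74.5% of calls that remained, in the same direction, after the trend was removed. The removal also brought in other calls, to 305 lower and 191 higher genes in all. Of the named calls 10 ended: Srf went from 0.26 (SE 0.06) to 0.08 (SE 0.07), Kcnh2 from 0.37 (SE 0.07) to 0.19 (SE 0.05), Nes from 0.31 (SE 0.07) to 0.19 (SE 0.06), Erbb2 from 0.35 (SE 0.06) to 0.22 (SE 0.07), Bmp7 from 0.30 (SE 0.06) to 0.21 (SE 0.07), Smad7 from 0.45 (SE 0.09) to 0.33 (SE 0.10) and Tbx3 from 0.42 (SE 0.08) to 0.33 (SE 0.08), all by a smaller fold, while Kcne1 from 0.44 (SE 0.09) to 0.39 (SE 0.09), Pdia4 from −0.30 (SE 0.07) to −0.26 (SE 0.06) and Rgs5 from −0.40 (SE 0.08) to −0.40 (SE 0.10) moved little, with adjusted p of 0.0512, 0.0564 and 0.0552.

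Of 30 endothelial genes 6 fell and 3 rose, and the 3 rises were lost without wild-type replicate 3 or any 1 deletion library. Whether a different share of endothelial cells contributed cannot be told apart from a change within them: 10 members passed in the rarer direction, adjusted over the list alone, but that count restates the pattern and decides nothing. The length and GC trend is argued against by the 8 of 9 called members that still passed after its removal, with both directions among them. A hypothesis is that expression shifted towards arterial and tip endothelial genes. The 12 measured of 14 such genes had a median log2 fold change of 0.26, above the bound of 0.2 set for this hypothesis (camera p = 0.00154, and p = 0.0486 with an estimated correlation). The median was 0.25 after the trend was removed, and at most 0.14 in size in the other 9 splits, where the lowest camera p was 0.00538. By construction those splits keep only a part of the difference between the groups. A smaller median there therefore does not count for the hypothesis. In limma 0 members passed over all genes, with 7 at an unadjusted p under 0.05, 6 of them higher and 1, Tspan18, lower (log2 fold change −0.13). Against these, 0 passed in edgeR and 3, all higher, in DESeq2. Adjusted over the list alone 5 passed in limma, among them Gja4 with a log2 fold change of 0.61, while Mecom, Nrp1 and Pgf had −0.0072, 0.025 and −0.0032. The Notch and neuregulin list went both ways, with 7 members higher and 4 lower adjusted over that list alone. Among them were Dll4 (0.75), Notch1 (−0.28) and Heyl (−0.88). The arterial and tip values may thus be a small shift and need other embryos.

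In the hypoxia and glycolysis list 7 of 26 members rose, Vegfa with the smallest p, and the list did not pass with an estimated correlation (adjusted p = 0.358). A single scaling factor per library shifts the list and all genes alike. It cancels in the distance between their medians, so that distance could not test it. Scaling that changes with expression level is argued against, since the list's median stayed 0.24 above that of all genes after quantile normalization. The length and GC trend is argued against by the 6 of 7 called members that still passed. Handling of the tissue before lysis cannot be told apart from an effect of the deletion: the 6 handling genes Fos, Jun, Junb, Egr1, Ier2 and Dusp1 had a median of 0.14 with an SD of 0.14, against 0.19 for all 26 members of the hypoxia list. This comparison was changed once its outcome was known: it was first made with the 7 called members, whose median of 0.39 lay further above than the SD and would have argued against handling, but those members were picked for their rise. Oxygen supply was not tested.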
